A study of Homo sapiens with 180 samples.

How the data were processed

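Expression was measured in 180 primary breast cancers on 1-colour oligonucleotide arrays, with 1 array per tumour. Per the labels, total RNA was isolated with Trizol or RNeasy, without a record of which kit served which tumour, and converted to biotin-labelled cRNA. The labels place every tumour in the same group, so no contrast between conditions was made. Outcome, receptor status and collection centre were not used here. Nothing in the labels states that each tumour came from a separate patient, so the p-values measure the spread between these samples.

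The deposited values are linear probe-set intensity, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version, the target level and any further scaling are not given in the sources used here. The table held 151 probe sets: 76 of a prognostic signature, 24 reference probe sets for scaling and 51 array controls. Intensities ran from 0.2 to 11500, with 0 missing values and 0 values at or below 0, and 0 pairs of arrays were identical. Array medians over the 151 probe sets ranged from 102.8 to 551.1, with a median of 220.3. The values are not centred and not logged, and whether the arrays were brought to a common level on probe sets outside this table is unknown. For arrays, their number limits the precision, and array signal gives no count from which an interval could be made.

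Gene names came from the platform annotation, in which 94 probe sets had 1 symbol, 2 had several and 55 had none. Of the signature probe sets, 67 were named and stood for 62 genes, and 9 are given by probe ID alone. Of the reference probe sets, 17 were named, all 17 as ribosomal protein genes. The annotation gives the bacteriophage cre spike-in probes a gene symbol that is not printed here. Pairs among these probe sets counted as pairs of the same gene and were left out of the pair tests. Probe sets of the other spike-ins and bacterial controls have no symbol. Pairs that read the same such control therefore stayed in the pair counts and in the control list. Chromosomes and gene order came from the GRCh38.p14 annotation.

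Intensities were taken to log2 with no pseudocount and no further scaling between arrays. Where a list needed 1 probe set per gene, the one with the highest mean was used. Every pair of probe sets that did not name the same gene was tested by Pearson's r with a two-sided permutation test of 100000 permutations, and Spearman's rho was computed beside it. The Benjamini-Hochberg procedure was applied over the 11308 pairs with a threshold of 0.05. The smallest p that the permutations can give is 1e-05. Each correlation was repeated without the 2 tumours farthest from the median of the x measure and within each block of sample numbers.

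Before the data were examined, 15 gene lists, the tests, the named-gene rule and 1 set of alternatives were fixed. No outside source is given for the lists, and several hold signature genes under both older and current symbols, such as HDGFL3, RFX7, MYRF and YIF1A. Some genes fit their list loosely, such as ZFP36L2 under chromatin and transcription. The lists are therefore not functional sets made independently of the signature's gene content. A list with at least 3 measured genes was tested by its mean pairwise r against 10000 random sets of the same size. These sets came from the whole array, control probe sets included, and were matched on mean level where the array allowed. The minimum of 3 genes left 8 lists: cell cycle and DNA replication, immune cells, cell death, chromatin and transcription, signalling, cytoskeleton and adhesion, secretory pathway and protein turnover, and array controls. The oestrogen receptor and luminal, basal, ERBB2 amplicon and endothelial lists had 0 measured genes. The extracellular matrix list had 1 (COL2A1), the adipose list 1 (ACACB) and the epithelial list 2 (ABLIM1 and TACC2). List scores are means of z-scored log2 values, with genes shared by a pair of lists left out of both. Components were kept when their eigenvalue exceeded the 95th percentile of 1000 data sets with each probe set permuted. A probe set was called separated into 2 clusters when a mixture of 2 Gaussians improved the BIC by more than 10, Ashman's D exceeded 2, the smaller cluster held at least 10% and the density had a trough. No pair or list member with such a probe set is given a pooled correlation, but counts of pairs, list means, scores and components include them, and were repeated without them.

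The rule named ESR1, PGR, ERBB2, MKI67 and TOP2A where measured, of which 0 had a probe set; for each tested list the 4 members that correlated best and the 1 that correlated worst with the others; the 10 largest and 5 smallest SDs among probe sets above the median level; the 5 most positive and 5 most negative pairs; genes with several probe sets; up to 10 separated probe sets; and the 5 highest and 3 lowest loadings of the first 3 components. The strongest pairs inside the signature, and genes that differed between RNA-quality clusters or number blocks, were named after their values were seen.

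RNA quality was read from the 3'/5' log2 signal ratio, averaged over ACTB and GAPDH. The sample numbers have 1 gap far larger than the others, and the 144 tumours before it and the 36 after it were treated as technical blocks. The labels do not say what the gap stands for. Differences between blocks and between clusters of the 3'/5' ratio were tested by the same permutations, with adjustment over the 76 signature and the 24 reference probe sets separately.

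This first set of alternatives held median centring of each array, quantile normalization, log2(value + 16), omission of the dimmest 25% of probe sets, the mean of all other probe sets as a covariate, each block alone, subtraction of block means, Spearman's rho, omission of the 5% of arrays least like the others, the mean of all probe sets of a gene, and random sets not matched on level. Chosen after the data were seen were centring on the reference probe sets, regression on the 3'/5' ratio, regression on the ratio, the reference mean and the block together, omission of arrays with a GAPDH 3'/5' ratio above 3, omission of probe sets separated into 2 clusters, and random sets drawn from the signature alone.

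The scripts were tested on simulated data with 151 probe sets and 180 tumours. Of planted pairs with r of 0.2, 4 of 105 were recovered, with 0 of 11203 other pairs called. At r of 0.3, 85 of 104 planted pairs were recovered with 8 of 11204 others called, and at r of 0.5, 105 of 105 with 3 of 11203. Planted lists had an adjusted p of 0.0004 and unplanted ones between 0.403 and 0.627. Clusters 5 SD apart were found in 100 of 100 data sets, and 0 of 100 single normal distributions were called. The clusters of the 3'/5' ratio lie closer, with an Ashman's D of 2.02, just past the limit. No skewed single distribution was simulated, so these data sets do not show how such a shape would be called. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.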

Results

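The series measured a prognostic gene signature on arrays in 180 lymph node-negative primary breast cancers. It holds 1 group, and the questions that the data can answer are how far each transcript varied between tumours and which transcripts varied together. Each array gave 76 signature probe sets, 24 reference probe sets and 51 controls, at median intensities from 102.8 to 551.1 per array. Over the 180 tumours the mean log2 intensity of the signature was 7.14 ± 0.44 (SD) and that of the reference probe sets was 12.63 ± 0.26.

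Among probe sets above the median level, signature transcripts differed most between tumours for EEF1A2, a tissue-restricted translation elongation factor, and for DUSP4, a phosphatase that acts on MAP kinases. EEF1A2 had a mean log2 intensity of 8.0 ± 1.86 (SD, n = 180), and its 95th percentile was 52.3-fold above its 5th. The DUSP4 probe set 204014_at had a mean of 8.54 ± 1.65 and a 29.6-fold range. The next were CD44, a hyaluronan receptor, with SDs of 1.20 and 1.08 on its probe sets, TNFSF10 (TRAIL, a death-receptor ligand) at 1.11 and GOLM1, a Golgi membrane protein, at 1.11. They were followed by SMC4, a condensin subunit, at 1.06 on probe set 201663_s_at and complement component C3 at 1.03. The 5' probe sets of the control transcripts GAPDH and ACTB also ranked among the 10 most variable, with SDs of 1.31 and 1.21.

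The most even transcripts at that level were ribosomal protein genes and spike-ins. RPL34 had an SD of 0.19 and RPS24 of 0.16, and the cre spike-in probe sets AFFX-CreX-3_at, AFFX-r2-P1-cre-5_at and AFFX-r2-P1-cre-3_at had SDs of 0.18, 0.16 and 0.14. The median SD was 0.87 over the signature (bootstrap SD 0.025) and 0.29 over the reference probe sets. It was 0.27 over the 9 hybridisation spike-in probe sets whose IDs begin with AFFX-r2-Ec or AFFX-r2-P1. The 95:5 percentile fold of the signature had a median of 7.04, ran from 2.80 for ANAPC15, a subunit of the anaphase-promoting complex, to 336 for COL2A1, the type II collagen chain of cartilage, and exceeded 10 for 24 of 76 probe sets. COL2A1, singled out after its values were seen, had a median intensity of 12.5 and a 95th percentile of 733. Of the signature probe sets, 17 had medians at or under 27.8, the brightest median of the 27 bacterial controls, and their spread includes background.

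**Figure D1:**
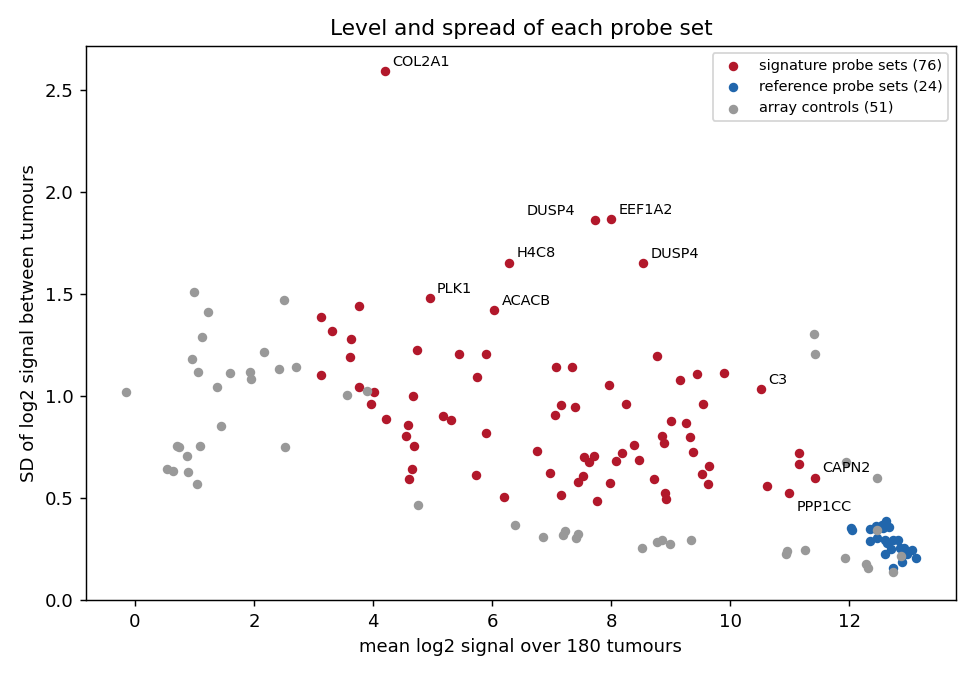
Mean log2 intensity (x axis) against the SD of the log2 intensity between 180 tumours (y axis), 1 point per probe set, for 76 signature, 24 reference and 51 control probe sets. Reference probe sets lie at a median SD of 0.29 and signature probe sets at 0.87, with COL2A1, EEF1A2, DUSP4 and H4C8 the highest signature genes.

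The 5 closest pairs inside the signature joined SMC4, FEN1 and CENPU to other signature probe sets. SMC4 (201663_s_at) varied with ATAD2, a bromodomain ATPase, at r = 0.806 (rho = 0.781), and with NCAPG2, a condensin II subunit, at r = 0.806 (rho = 0.786). FEN1, the flap endonuclease of DNA replication, followed KPNA2, an importin, at r = 0.804 (rho = 0.779). CENPU, a centromere protein, followed the unnamed probe set 205034_at at r = 0.794 (rho = 0.794), which also followed SMC4 (201664_at) at r = 0.778 (rho = 0.760). Each had a permutation p of 1e-05 for r and rho, the smallest that the permutations can give, and adjusted values of 4.52e-05 and 4.81e-05 over 11308 pairs. Without the 2 farthest tumours the 5 correlations were 0.786, 0.793, 0.801, 0.778 and 0.763. Before the number gap they were 0.812, 0.833, 0.812, 0.789 and 0.769, and after it 0.786, 0.674, 0.773, 0.824 and 0.833.

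The most negative pair of the whole array joined PLK1, a mitotic kinase, to ACACB, the mitochondrial acetyl-CoA carboxylase that restrains fatty acid oxidation. Their r was -0.421 (rho = -0.420, p = 1e-05 for each, adjusted 4.52e-05 and 4.81e-05), -0.416 without the 2 farthest tumours, -0.403 before the gap and -0.508 after it. It stayed negative and past the threshold in all 15 alternatives, from -0.539 to -0.291, and was -0.346 after regression on the 3'/5' ratio. The unnamed probe set 219510_at was also lower where ACACB was higher (r = -0.264, p = 0.00044, adjusted 0.00143; rho = -0.267, p = 0.00039, adjusted 0.00134), at -0.236 without the 2 farthest tumours and -0.267 and -0.246 in the blocks; of 15 alternatives only the tumours after the gap alone lost the call (adjusted p = 0.442). DUSP4 (204015_s_at) opposed COL2A1 (r = -0.295, p = 7e-05, adjusted 0.000264; rho = -0.206, p = 0.0062, adjusted 0.0158), at -0.249 without the 2 farthest tumours and -0.295 and -0.339 in the blocks, and of 14 alternatives it too lost its call only after the gap (adjusted p = 0.224). FUT3, a fucosyltransferase of the Lewis antigens, and ACACB gave r = -0.222 (p = 0.00277, adjusted 0.00762; rho = -0.209, p = 0.00477, adjusted 0.0125), at -0.211 without the 2 farthest tumours, -0.276 before the gap and -0.0896 after it. This pair kept its call in 10 of 14 alternatives and lost it after the gap, after regression on the 3'/5' ratio (r = -0.111, adjusted p = 0.247), with the GAPDH ratio limited to 3 (-0.168, 0.107) and with the ratio, reference mean and block regressed out (-0.0456, 0.745). COL2A1 and FUT3, at median intensities of 12.5 and 16.85, lie under the brightest bacterial control median of 27.8. PLK1, at 31, lies just above it. The correlations of these genes therefore include background.

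Most signature pairs varied in the same direction under the deposited scale, a count that depended on the scaling. Of 2845 signature pairs, 1854 were positive and 17 negative past the threshold, with a median r of 0.236. Of these pairs 365 hold a probe set separated into clusters, and without such probe sets 1686 of 2480 were positive and 16 negative. The split was 748 positive to 277 negative with arrays centred on their medians, 348 to 348 after quantile normalization, 423 to 310 with the array-wide level as a covariate, and 1179 to 49 after centring on the reference probe sets. Reference probe sets were positive in 276 of 276 pairs, with a median r of 0.760, and pairs of a signature and a reference probe set had a median r of 0.321. Over the array 4937 pairs were positive and 421 negative, 47.4% of 11308.

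Among pairs of probe sets that do not name the same gene, spike-ins added to the hybridisation gave the highest correlations. AFFX-r2-Ec-bioD-5_at followed AFFX-r2-Ec-bioD-3_at at r = 0.950 and AFFX-BioDn-3_at at 0.949, and the cre probe set AFFX-CreX-5_at followed the bioD probe sets at 0.940 and 0.930 (rho from 0.925 to 0.943, p = 1e-05 and adjusted 4.52e-05 for each r). The bioD probe sets read the same spike-in but carry no gene symbol, so the pairs among them are not pairs of different transcripts. The 5' probe sets of ACTB and GAPDH, separated into clusters, correlated at 0.834 and 0.765 within the ACTB clusters, the lower of 49 tumours, and at 0.883 and 0.673 within the GAPDH clusters, the lower of 55. Among the negative pairs, AFFX-BioDn-5_at and 5' GAPDH gave -0.128 and -0.120 within clusters, AFFX-BioDn-5_at and 5' ACTB -0.253 and -0.151, and 5' ACTB and AFFX-r2-Ec-bioB-5_at -0.231 and -0.122. The middle ACTB probe set and AFFX-r2-Ec-bioB-5_at gave r = -0.396 (rho = -0.289, p = 1e-05 and 9e-05, adjusted 4.52e-05 and 0.000353), at -0.416 without the 2 farthest tumours and -0.387 and -0.388 in the blocks. It kept its call in 13 of 15 alternatives and lost it after the gap (adjusted p = 0.137) and after regression on the 3'/5' ratio, where r fell to -0.101 (adjusted p = 0.30).

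The 9 measured cell cycle and DNA replication genes varied together more than random sets from the array on the deposited scale. Their mean pairwise r was 0.518, against 0.109 to 0.330 for the central 95% of random sets (adjusted p = 0.0008 over 8 lists). All 9 members passed the threshold for correlation with the mean of the others. So did every member of the other gene lists, so passing does not set this list apart. KPNA2 correlated best (r = 0.853), followed by NCAPG2 (0.822), FEN1 (0.814) and SMC4 (0.793), and the weakest was ORC3, a subunit of the origin recognition complex (0.295). Random sets from the array can hold control probe sets as well as genes. Because the signature was chosen from breast tumours and the array holds little else, random sets from the signature alone, added after the data were seen, are a closer comparison. The list also exceeded these (0.199 to 0.393, adjusted p = 0.0008). With arrays centred on their medians the mean r was 0.30, with an adjusted p of 0.181 against array-wide sets and 0.0008 against signature sets. Under that centring the control list itself had a mean r of 0.308, so array-wide sets there can include controls that vary together.

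The 10 chromatin and transcription genes had a mean r of 0.414 (random sets 0.128 to 0.326, adjusted p = 0.00107). SUPT16H, a subunit of the histone chaperone FACT, led at 0.808, with CBX3, a heterochromatin protein, at 0.765, HDGFL3 at 0.685, the zinc-knuckle protein ZCCHC8 at 0.680 and MYRF the weakest at 0.353, and all 10 members passed. ATAD2 and the histone gene H4C8 stand in this list and in the cell cycle list. Against signature sets the adjusted p was 0.0203, and it was 0.184 after regression on the 3'/5' ratio. Against array-wide sets the call was lost under median centring (r = 0.159, adjusted p = 0.939), quantile normalization (0.0865, 0.133) and the array-wide covariate (0.0892, 0.386). The 3 cell death genes had a mean r of 0.269 (adjusted p = 0.0232, and 0.104 against signature sets), with TNFSF10 at 0.424 and GAS2 at 0.235. That call was kept in 8 of 17 alternatives. It was lost, among others, under median centring (adjusted p = 0.852), quantile normalization (0.0915), reference centring (0.133), before the gap (0.237) and against sets not matched on level (0.562). BCL2L14, a BCL2 family member, is separated into clusters and stands in 2 of the 3 pairs behind that mean. Without it the list has too few genes to test, so the call is not firm.

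The other gene lists did not exceed random array-wide sets on the deposited scale with all probe sets. The 5 immune genes had a mean r of 0.490 (adjusted p = 0.177, and 0.427 against signature sets). Against signature sets they passed under median centring (0.370, adjusted p = 0.0075), quantile normalization (0.297, 0.0091) and the array-wide covariate (0.311, 0.0192). ARHGDIB stood at 0.703, the cytokine IL18 at 0.646, TNFSF13 (APRIL) at 0.632, TNFSF10 at 0.577 and C3 at 0.564. The 6 secretory genes had 0.417 (adjusted p = 0.182), from AP2A2, a clathrin adaptor subunit, at 0.680, the proteasome ATPase PSMC2 at 0.639, YIF1A at 0.614 and the sialic acid transporter SLC35A1 at 0.565 to GOLM1 at 0.440. The 10 cytoskeletal genes had 0.321 (adjusted p = 0.0733), led by the centrosomal CEP57 at 0.664, the actin-binding ABLIM1 at 0.652 and TACC2 at 0.626, with CAPN2 and MYH2 separated into clusters but part of that mean. Without the separated probe sets the cytoskeletal list, at 0.362 over 8 genes, and the immune list, at 0.490, passed against the remaining array (adjusted p = 0.0098 and 0.0406). The 5 signalling genes had 0.189 (adjusted p = 0.437), with CNKSR1 at 0.459, PPP1CC at 0.363, NEURL1 at 0.303, DUSP4 at 0.203 and GABRQ, a GABA receptor subunit, at 0.20. Over the 48 member tests of all lists the adjusted p of each member given with a value was at most 0.00749 for r, and rho was past the threshold for each but DUSP4 (0.141, adjusted p = 0.0577). The 44 array controls had 0.136, below random sets (adjusted p = 0.0008), but above them under median centring (0.308), quantile normalization (0.108), the array-wide covariate (0.118), reference centring (0.227), omission of the dimmest 25% (0.578) and regression on the ratio, reference mean and block (0.145).

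**Figure D2:**
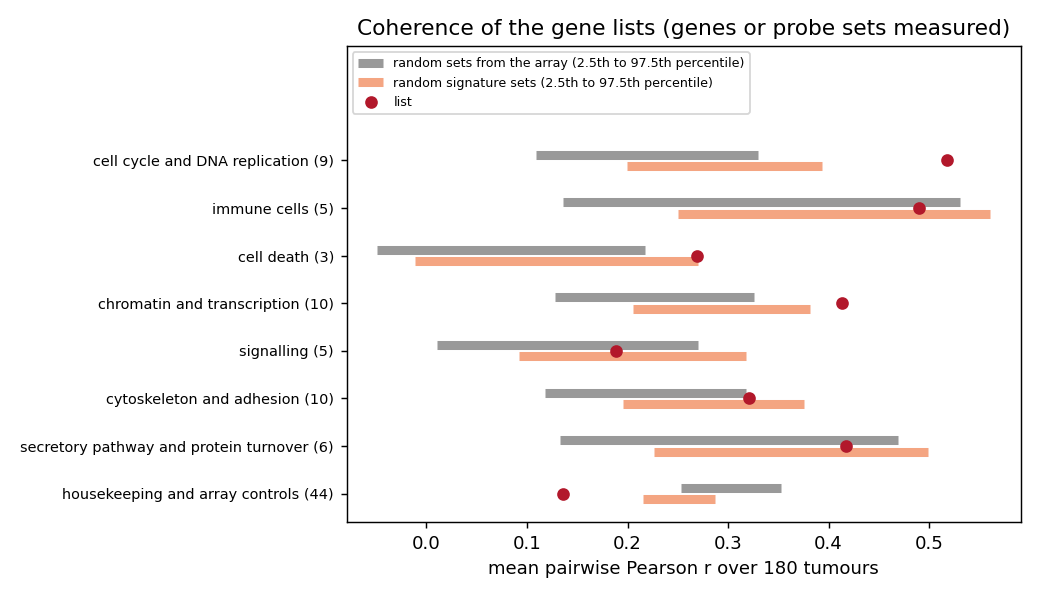
Mean pairwise Pearson r over 180 tumours (x axis) for 8 gene lists (y axis, number of genes or control probe sets in brackets). Red points are the lists, and the bars span the central 95% of random sets from the array (grey) and from the signature (orange), where the cell cycle list at 0.518 lies above both under the deposited scale; with arrays centred on their medians it lies above signature sets alone, and the controls, here below the random sets, lie above them.

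List scores rose together in 22 of 28 pairs past the threshold under the deposited scale, 21 of 21 among the gene lists and 1 of 7 with the controls. Positive correlations numbered 16 under median centring, 7 with the array-wide covariate and 6 after quantile normalization. The highest was that of the cytoskeletal and secretory genes (r = 0.812, rho = 0.749, p = 1e-05 for each, adjusted 1.47e-05, 0.804 without the 2 farthest tumours, 0.829 and 0.719 in the blocks). The cell cycle score followed the chromatin score at r = 0.733 (rho = 0.672, p = 1e-05 for each, adjusted 1.47e-05, 0.704 without the 2 farthest tumours, 0.759 and 0.658 in the blocks), and this relation stayed positive and past the threshold in 17 of 17 alternatives, from 0.261 to 0.759. The cell cycle and immune scores gave 0.289 on the deposited scale (rho = 0.254, p = 0.00012 and 0.00067, adjusted 0.000168 and 0.000893, 0.245 without the 2 farthest tumours, 0.318 and 0.0690 in the blocks), and the direction turned to -0.362 under median centring, -0.439 under quantile normalization and -0.393 with the array-wide covariate. The cell cycle score with the cytoskeletal score turned in the same way, from 0.480 (rho = 0.426, p = 1e-05 for each, adjusted 1.47e-05, 0.438 without the 2 farthest tumours, 0.504 and 0.322 in the blocks) to -0.290, -0.409 and -0.354.

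Different probe sets of the same gene followed each other closely for all 5 signature genes with more than 1. CD44 gave r = 0.989 (rho = 0.990), TNFSF13 0.950 (0.947), DUSP4 0.918 (0.923), SMC4 0.898 (0.884) and HDGFL3 0.871 (0.846), each with p = 1e-05, which is also the adjusted value over 17 pairs. Without the 2 farthest tumours r ran from 0.858 for HDGFL3 to 0.989 for CD44. In the blocks it was lowest for HDGFL3 before the gap (0.855) and for SMC4 after it (0.889).

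Over all probe sets of the array 7 directions of shared variation exceeded chance, and 6 did so over the signature. The first held 25.2% of the variance and was carried by ribosomal protein genes and by PPP1CC, a catalytic subunit of protein phosphatase 1. RPS13 loaded at r = 0.871, PPP1CC at 0.842, 200017_at at 0.833, RPS7 at 0.833 and 200092_s_at at 0.830, with the spike-ins AFFX-r2-Ec-bioB-3_at (-0.269), AFFX-r2-Ec-bioC-5_at (-0.237) and AFFX-BioB-M_at (-0.220) lowest. It followed the mean of the reference probe sets at r = 0.875, which its own members contribute to. The second (12.2%) ran from spike-ins (AFFX-r2-Ec-bioC-3_at 0.901, AFFX-BioC-3_at 0.895, AFFX-CreX-3_at 0.893, AFFX-BioDn-5_at 0.886, AFFX-CreX-5_at 0.885) to FUT3 (-0.371) and the 5' GAPDH and ACTB probe sets, and was lower after the number gap (r = -0.455 with the block). The third (7.31%) set PLK1 (0.704), the cell cycle protein GTSE1 (0.637), 219510_at (0.625), 205034_at (0.589) and CENPU (0.570) against ACACB (-0.459) and the ribosomal genes RPL17 (-0.416) and RPL21 (-0.409).

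Inside the signature the first component held 29.8% and rose with PPP1CC (0.852), CBX3 (0.836), SUPT16H (0.793), CEP57 (0.779) and YIF1A (0.768), with COL2A1 (0.0882), ACACB (0.118) and 219724_s_at (0.146) lowest. It too followed the reference mean (r = 0.688). The second (9.62%) ran from PLK1 (0.712), 219510_at (0.604), 205034_at (0.577), ATAD2 (0.555) and CENPU (0.547) to C3 (-0.540), ACACB (-0.537) and ZFP36L2, an RNA-binding protein of mRNA decay (-0.495). The third (5.03%) ran from FUT3 (0.581), NEURL1 (0.400), PGAP6 (0.377) and RFX7 (0.337), with ZNF362 among the 5 highest, to ORC3 (-0.530), SLC35A1 (-0.446) and HDGFL3 (-0.393). Loadings are correlations with the component's own members, and neither they nor the correlations of components with the reference mean or block carry a test.

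Over the array 15 probe sets separated into 2 clusters, 5 of them in the signature, 10 among controls and 0 in the reference set. By improvement in BIC the first were 5' ACTB (cluster means 10.12 and 12.06) and 5' GAPDH (10.09 and 12.12), then bacterial control probe sets near background (AFFX-r2-Bs-lys-M_at, AFFX-r2-Bs-lys-3_at, AFFX-r2-Bs-dap-5_at, AFFX-r2-Bs-lys-5_at, AFFX-r2-Bs-phe-M_at, AFFX-DapX-M_at and AFFX-PheX-M_at). The zinc-finger gene ZNF362 was the only signature gene among the first 10, with means of 2.67 and 4.80 and 89.9% of tumours in the higher cluster. The remaining signature probe sets were MYH2, BCL2L14, CAPN2 and 207118_s_at. CAPN2, a calpain, was the only bright one, with means of 10.23 and 11.58.

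Signs of RNA quality differed between tumours. The 3'/5' ratio separated into a high cluster of 52 tumours at 2.68 ± 0.97 (mean log2 ± SD) and a low cluster of the remaining tumours at 0.66 ± 0.40. PLK1 was lower in the high-ratio tumours, at 4.05 ± 1.48 against 5.32 ± 1.32, and RFX7, a transcription factor, at 4.32 ± 1.42 against 5.89 ± 0.72. CD44 (-1.17 and -1.03), PGAP6 (-1.18), FUT3 (-1.22), ATAD2 (-1.11), FEN1 (-1.02), YIF1A (-0.89), COL2A1 (-1.38) and ZNF362 (-0.71) were lower too, while ACACB was 0.77 higher (6.59 ± 1.13 against 5.82 ± 1.47, adjusted p = 0.0019). These 11 lower probe sets of 10 genes and ACACB were named because they kept direction and call on the deposited scale and under the 4 other scalings, though many shrank. They were picked from 49 lower and 1 higher on the deposited scale, and the rest lost their call under at least 1 scaling. With the array-wide covariate YIF1A was at -0.29, FEN1 at -0.37, CD44 at -0.39 and -0.48, ATAD2 at -0.45 and PLK1 at -0.69. FUT3, COL2A1 and ZNF362, at median intensities of 16.85, 12.5 and 26.15, lie under the bacterial control level of 27.8, so their log differences include background. With log2(value + 16) they were at -0.49, -0.87 and -0.37, still past the threshold. PLK1 and RFX7 also had means under that level in the high-ratio tumours, and with the offset their differences shrank from -1.26 to -0.73 and from -1.57 to -0.94. Not every cell cycle gene was lower, as ORC3 (-0.06), GTSE1 (-0.07) and CENPU (-0.28) did not differ past the threshold on the deposited scale. ORC3 and GTSE1 were higher under median centring (0.26 and 0.25, adjusted p = 0.0285 and 0.0107) and quantile normalization (0.26 and 0.28, adjusted p = 0.0305 and 0.0043).

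Over all 76 signature probe sets the number called depended on the scale. On the deposited scale 49 of 76 were lower and 1 higher in the high-ratio tumours, with a median of -0.32, while 12 of 24 reference probe sets were lower, with a median of -0.10. The signature split was 35 lower to 1 higher after reference centring (median -0.21) and 21 to 6 under median centring (median 0.0015). It was 18 to 10 after quantile normalization (median 0.0408) and 12 to 6 with the array-wide covariate (median -0.0033). Apart from reference centring, these scalings draw on the signature itself and can remove a shift that it shares. Their medians were smaller in size than the bootstrap SD on the deposited scale (0.075). That SD does not measure the spread on those scales, so no direction is read from these medians. Within the low-ratio cluster 17 signature probe sets fell with the ratio and 1 rose, and within the high-ratio cluster 2 fell and 0 rose. The number that fell ran from 6 to 21 over alternatives in the low-ratio cluster, and was 10 under median centring and 8 with the array-wide covariate. In the high-ratio cluster it kept within 1.5 times in 5 of 12 alternatives, and was 1 under median centring, quantile normalization and reference centring. It was 0 with the array-wide covariate, with the GAPDH ratio limited to 3 and without the arrays least like the others. On the deposited scale the 2 were PLK1 (r = -0.440, p = 0.00097, adjusted 0.0369; rho = -0.496; -0.460 without the 2 farthest tumours) and RFX7 (r = -0.517, p = 1e-04, adjusted 0.0076; rho = -0.448; -0.454 without them). The mean of all signature probe sets fell with the ratio in the low-ratio cluster (r = -0.245, p = 0.00576, adjusted 0.0288; rho = -0.214, p = 0.0157, adjusted 0.0577; -0.251 without the 2 farthest tumours; -0.204 and -0.242 in the blocks). So did the signalling score (r = -0.217, p = 0.0137, adjusted 0.0458; rho = -0.209, p = 0.0173, adjusted 0.0577; -0.234 without the 2 farthest tumours; -0.172 and -0.349 in the blocks). The cell cycle score fell about as much there (r = -0.250, p = 0.00438, adjusted 0.0288; rho = -0.228, p = 0.00948, adjusted 0.0577; -0.236 without the 2 farthest tumours; -0.30 and -0.179 in the blocks) and was not past the threshold in the high-ratio cluster (r = -0.254, p = 0.0694, adjusted 0.231; rho = -0.285, p = 0.0408, adjusted 0.121; -0.231 without the 2 farthest tumours).

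**Figure D3:**
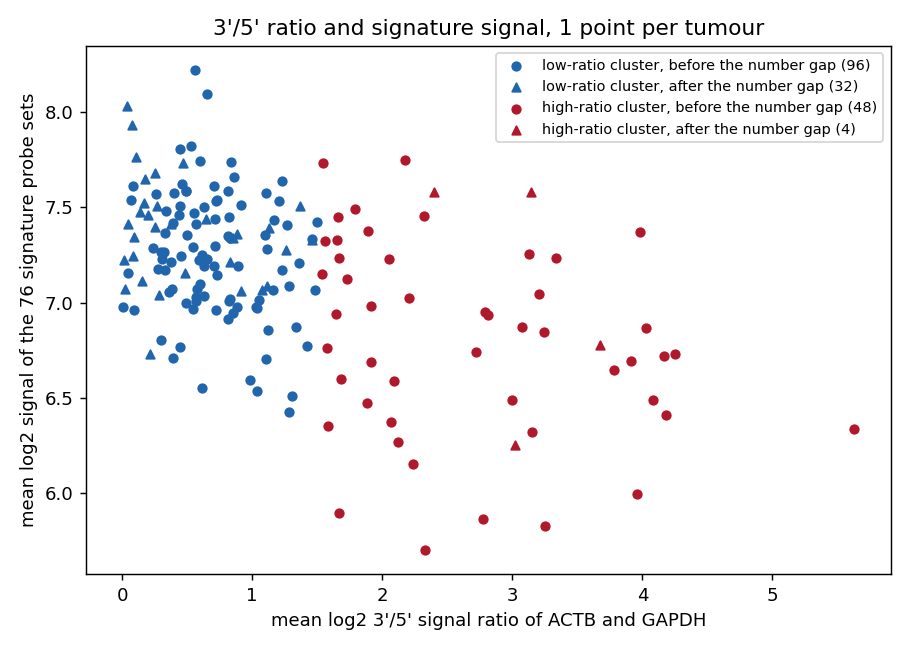
Mean log2 3'/5' signal ratio of ACTB and GAPDH (x axis) against the mean log2 intensity of the 76 signature probe sets (y axis), 1 point per tumour, coloured by ratio cluster, with circles before and triangles after the sample number gap. The 52 high-ratio tumours form a long tail with no empty gap before it. The median signature probe set was 0.32 lower there on the deposited scale (bootstrap SD 0.075). Under median centring (0.0015) and quantile normalization (0.0408), which draw on the signature itself, the difference was smaller than that bootstrap SD. That SD does not measure the spread on those scales.

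The 36 tumours after the number gap had higher signal for a group of signature genes. GAS2, a growth-arrest gene, stood at 5.32 ± 1.05 against 4.52 ± 0.92 before it, SAT1, the spermidine acetyltransferase, at 3.73 ± 1.05 against 2.98 ± 1.06, and CBX3 at 9.74 ± 0.60 against 9.28 ± 0.73. RFX7 (1.05), PGAP6 (0.69), both HDGFL3 probe sets (0.49 and 0.56), and the probe sets annotated to the ribosomal pseudogenes RPS4XP3 (1.18) and RPL23AP7 (0.60), whose signal can include related transcripts, were higher as well. These 9 probe sets were named because they were called higher on the deposited scale and under the 4 other scalings. SAT1 and GAS2, at median intensities of 9.15 and 26.4, lie under the bacterial control level, and with log2(value + 16) their differences were 0.30 and 0.53, still past the threshold. On the deposited scale 16 of 76 signature probe sets were higher after the gap and 0 lower (median 0.21), against 11 to 0 under median centring, 9 to 2 after quantile normalization, 12 to 1 with the array-wide covariate and 21 to 0 after reference centring. After regression on the 3'/5' ratio 8 were higher (median 0.0861). Of the 9 named, 7 kept their call there, though RFX7 shrank from 1.05 to 0.58 and PGAP6 from 0.69 to 0.39, while CBX3 fell from 0.46 to 0.27 (adjusted p = 0.118) and HDGFL3 on 216693_x_at from 0.56 to 0.39 (adjusted p = 0.0683). The mean of the 9 AFFX-r2-Ec and AFFX-r2-P1 spike-in probe sets was lower after the gap (9.44 ± 0.23 against 9.70 ± 0.21, p = 1e-05). The 3'/5' ratio was lower too (0.77 ± 0.94 against 1.36 ± 1.12, p = 0.00393), so the blocks also differed in RNA quality.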

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

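Centring on reference probe sets, the regressions on the 3'/5' ratio, the GAPDH ratio limit, random sets from the signature alone, omission of separated probe sets, the counts between ratio clusters and between number blocks, and the differences of named probe sets under other scalings, offsets and regressions were chosen only after the data were seen. Over 758 recomputed values, 608 were kept. A count was kept when it stayed within 1.5 times its value on the deposited scale. A median SD or median difference was kept within its bootstrap SD, and a tested value when it kept its direction and side of the threshold. The correlation between probe sets of the same gene (0.757 to 0.903 for the signature gene whose probe sets were least alike) was kept in all alternatives run. So were the number of components over the array (5 to 10), PLK1 with ACACB, the 5 closest signature pairs and the cell cycle score with the chromatin score. Except where a setting uses fewer tumours or probe sets, the cause of a change was not tested. The 17 signature probe sets at or under bacterial control level limit what dim transcripts can show.

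With each array centred on its median, the median SD of the signature was 0.735 against 0.873, and 748 signature pairs were positive and 277 negative. Coherence exceeded random sets for 1 list rather than 3: cell cycle 0.30, cell death 0.223 and chromatin 0.159 were no longer past the threshold, secretory genes fell below the random median at 0.134, and controls rose above it at 0.308. The cell cycle score turned negative with the scores of cell death (-0.218), cytoskeleton (-0.290), controls (-0.412), immune (-0.362), secretory (-0.0892) and signalling genes (-0.199). In the high-ratio cluster 21 signature probe sets were lower and 6 higher with a median of 0.0015, the within-cluster counts of probe sets falling with the ratio were 10 (low) and 1 (high), and the median difference after the number gap was 0.12.

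After quantile normalization the median SD was 0.733, 2761 pairs were called, and signature pairs split 348 to 348. Cell death (0.120) and chromatin (0.0865) lost their calls, immune genes gained 1 (0.297) and controls lay above random sets (0.108). Positive score correlations numbered 6, and the cell cycle score turned against cell death (-0.269), cytoskeleton (-0.409), controls (-0.324), immune (-0.439), secretory (-0.147) and signalling (-0.159). In the high-ratio cluster 18 were lower and 10 higher (median 0.0408), 1 fell within that cluster, and after the gap 9 were higher and 2 lower (median 0.0583).

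With the array-wide level as a covariate the median SD was 0.728, 2971 pairs were called and signature pairs split 423 to 310. Chromatin lost its call (0.0892), signalling fell below the random median (-0.0325) and controls rose above it (0.118). Positive score correlations numbered 7, and the cell cycle score turned against cell death (-0.313), cytoskeleton (-0.354), controls (-0.197), immune (-0.393) and signalling (-0.184). In the high-ratio cluster 12 were lower and 6 higher (median -0.0033), 8 fell within the low and 0 within the high cluster, and after the gap 1 was lower (median 0.0489).

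After centring on the reference probe sets the median SD was 0.798 and signature pairs split 1179 to 49. Cell death lost its call (0.198), immune genes gained 1 (0.369) and controls lay above random sets (0.227). The median in the high-ratio cluster was -0.21, and 1 probe set fell within it. With the ratio, reference mean and block regressed out the median SD was 0.724, 1944 pairs were called and signature pairs split 815 to 29, while cell death lost its call (0.158), immune genes gained 1 (0.343), controls lay above random sets (0.145) and the cell cycle score with cell death was -0.0179. With the 3'/5' ratio alone regressed out the median SD was 0.786, 9 probe sets were separated against 15, and 8 signature probe sets were higher after the gap (median 0.0861). With the GAPDH 3'/5' ratio at most 3, which left out 39 tumours, the median SD was 0.784, 20 probe sets were lower and 0 higher in the high-ratio cluster, 0 fell within it, and the median after the gap was 0.12.

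Without the dimmest 25% of probe sets the median SD was 0.782, 5 probe sets were separated, cell death lost its call (0.269), cytoskeleton gained 1 (0.377), controls lay above random sets (0.578) and their score turned against the cell cycle score (-0.0274). With log2(value + 16) the median SD was 0.640 and cytoskeleton passed (0.324). In the 36 tumours after the gap, a smaller sample, the median SD was 0.759, 1051 pairs were called, 282 signature pairs were positive and 3 negative, 14 score correlations were called and 14 of them positive, 3 signature components and 2 separated probe sets were found, 6 probe sets fell with the ratio in the low cluster and cytoskeleton passed (0.270). Among the tumours before it cell death lost its call (0.196), and 11 and 1 probe sets fell with the ratio in the low and high clusters. With block means subtracted cell death was at 0.234 (adjusted p = 0.0572, range over alternatives of mean r 0.120 to 0.408) and 10 fell within the low cluster. Without the 5% of arrays least like the others the median SD was 0.820 and 0 fell within the high cluster.

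Against random sets not matched on level, immune (0.490) and secretory genes (0.417) passed and cell death (0.269) did not. Against random sets from the signature alone cell death (0.269) lost its call and signalling (0.189) lay below the random median. Without the probe sets separated into clusters, which leaves 0 of them by construction, the immune (0.490) and cytoskeletal (0.362) lists passed, and the cell death list had too few genes for a value. The regressions on the ratio could not be applied to counts between ratio clusters, nor the block settings to counts between blocks, and the high-ratio cluster held 4 tumours after the gap, too few for a value.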

Other observations

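The tests of signal against the 3'/5' ratio within its clusters, and of reference centring between the clusters, were chosen only after the results were seen. SLC35A1, the Golgi transporter of CMP-sialic acid, and ORC3 lie on chromosome 6 of GRCh38.p14 with 1 protein-coding gene between them, and their signals rose together in the tumours (r = 0.709, rho = 0.682, p = 1e-05, adjusted 4.52e-05 and 4.81e-05 over 11308 pairs; 0.719 without the 2 farthest tumours; 0.701 and 0.743 in the blocks). Their r was 0.567 after regression on the 3'/5' ratio, the reference mean and the block. MYRF and FEN1 on chromosome 11 also have 1 protein-coding gene between them. Their r was lower, at 0.334 (0.231 after that regression, 0.372 and 0.0875 in the blocks). MYRF, at a median intensity of 13.35, lies under the bacterial control level of 27.8. Background can lower its r, so this pair cannot show whether closeness goes with a high r. YIF1A, a protein of transport between endoplasmic reticulum and Golgi, and FEN1 on chromosome 11 gave r = 0.760 (0.626 after that regression), and PPP1CC and ZCCHC8 on chromosome 12 gave 0.731 (0.677), and neither pair is adjacent. These pairs were picked after their values were seen.

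The SMC4 transcript read differently by its probe sets. In the high-ratio tumours 201663_s_at was 1.01 lower and 201664_at 0.29 lower on the deposited scale, and under median centring, quantile normalization and the array-wide covariate the sign for 201664_at turned to 0.04, 0.08 and 0.24. With that covariate 201663_s_at was 0.26 lower and no longer past the threshold (adjusted p = 0.099). The log ratio of the pair fell as the 3'/5' ratio rose within the low-ratio cluster (r = -0.559, adjusted p = 2.5e-05) and within the high-ratio cluster (r = -0.567, adjusted p = 0.00015). For HDGFL3 it rose within the low-ratio cluster (r = 0.473, adjusted p = 2.5e-05), and r was 0.195 in the high-ratio cluster (adjusted p = 0.373). The probe sets of CD44, DUSP4 and TNFSF13 showed no shift past the threshold.

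The cell cycle genes varied together, and RNA quality, array-wide level and the number blocks were tested as sources. After regression on the 3'/5' ratio their mean r was 0.486 against 0.174 to 0.358 for random signature sets, and with the array-wide level as a covariate 0.334 against -0.0219 to 0.0961, each with an adjusted p of 0.0008. The lower of the mean r within the blocks was 0.518. These values argue against each of the 3 as the whole source. A shared share of dividing cells is a hypothesis that may fit the rest, and it was not tested because no other measure of proliferation was used here.

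Signature signal was lower where the 3'/5' ratio was higher on the deposited scale. There 100 splits of the 180 tumours into sets of the same sizes were compared, 1 of them the real one. The real split gave 50 called probe sets and the others at most 12. A share of 1 of 100 is the smallest that this number of splits can give. The splits kept only the set sizes and ignored the order of the sample numbers, so they do not test against a drift along it. Between the clusters 1 factor per array does not account for signature and reference probe sets together. The median signature difference after reference centring was still -0.207 (bootstrap SD 0.056), and median centring left the median reference difference at 0.22. The median was 0.0015 under median centring, 0.0408 after quantile normalization and -0.0033 with the array-wide covariate. Each of these scalings draws on the signature probe sets themselves and can remove a shift that they share. Such small medians therefore cannot tell a shared shift of the signature from a scaling of the arrays. Which scale is right cannot be settled here. Signature minus reference probe sets gave -0.222 on the deposited scale and under median centring, as a shared factor leaves it unchanged, but 0.030 after quantile normalization and -0.061 with the covariate. Quantile normalization and the covariate use the signature itself, so their values cannot decide whether a scaling acted unequally on probe sets, for example by brightness. Such a scaling stays open. Within the clusters scaling and number block cannot be told apart from the pattern, because the highest median r was -0.0702 after reference centring (bootstrap SD 0.049) and -0.0725 within blocks (bootstrap SD 0.047), too close to the limit of -0.1 set for the tests. The position of a probe set in its transcript may contribute, as the log ratio moved with the 3'/5' ratio for 2 of the 5 genes with 2 probe sets, SMC4 and HDGFL3. No biological explanation was tested. The higher signal of 16 signature probe sets after the number gap was likewise reached by 1 of 100 splits, the real one, with at most 3 in the others. These splits also ignored the order of the sample numbers, so they cannot tell a step at the gap from a drift along the numbers. The meaning of the gap stays open.

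A hypothesis that signature genes of the same chromosome vary together, as shared copy number gains could produce, was not borne out for whole chromosomes. The comparison pools pairs at any distance, such as CNKSR1 and CAPN2 with 1502 protein-coding genes between them. It therefore does not test gains of a part of a chromosome. Over 61 genes the 110 pairs on the same chromosome had a mean r of 0.285 and the 1720 others 0.267, a difference of 0.0184 (one-sided p = 0.218 over 10000 shuffles of the chromosome labels). The difference was 0.0092 after regression on ratio, reference mean and block and 0.0165 without the cell cycle genes, and with no difference to explain these values decide nothing about those sources.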
